A study of Nitratidesulfovibrio vulgaris with 6 samples.

How the data were processed

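RNA from 6 samples of Desulfovibrio vulgaris Hildenborough was sequenced on an Illumina instrument, per the labels' protocols: 3 control samples without free nitrous acid (FNA) and 3 samples with FNA at 4 µg N/L. Replicates were numbered in order of deposit and pair nothing. The labels' protocols describe further FNA levels of 1.0 and 8.0 µg N/L, which are not analysed here.

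The values analysed are the authors' FPKM, 1 per gene and group, in a table laid out as Cuffdiff writes it, per the file headers. The submitters' processing notes name Cufflinks 2.2.1 and Cuffdiff. Aligner, genome version, annotation and the use of strand in counting are not given in the sources used here. The deposited log2 fold change is the log2 ratio of FNA over control, with a largest difference of 1.2e-05 from the ratio of the FPKM values. The deposited test statistic is a score per gene, and dividing the log2 fold change by it gave the implied standard error used here. The deposited p-value and q-value are Cuffdiff's: the lowest p is 5e-05, reached by 480 genes, and recomputing Benjamini-Hochberg adjustment over the 2702 tested genes gave the deposited q within 5.2e-07. Protein length in the table is another value the authors deposited and was not used.

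For 73 genes, 43 of them tested, the FPKM of at least 1 group reads as a spreadsheet error in place of a number. Such genes keep the authors' call but have no direction here, so tests of direction ran on 2659 genes. All 86 rows of ribosomal, transfer and other structural RNA genes are listed at 0 in both groups, so a 0 in this table can be a failed estimate; 2 called genes are listed at 0 in control and get no fold change. The table holds 0 genes with a locus tag of the megaplasmid, so the planned share of expression from it and the list of its genes were not analysed here. In 18 rows the gene and its tag or product disagree by position or name, and these were kept out of the lists. Of 3393 locus tags 2980 were found in the reference gene table of assembly ASM19575v1, which was used only to check names. Positions are those of the deposited table on the chromosome, counted from 1.

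Because the table holds group values only, the plan for that case was followed: the authors' calls at q under 0.05 are the main result. A normal test per gene of the deposited statistic was added after the data were seen, as an alternative only. Without values per sample, the planned tests on log values, the left-out replicates and other splits of the samples were not run. For 21 gene lists fixed before the data were examined, calls in each direction were compared with those of all other tested genes by Fisher's exact test, one-sided for an excess, with Benjamini-Hochberg adjustment over 40 tests of 20 lists. Members whose product contradicts the list, 32 entries in all, were dropped under a rule fixed before the data were examined, with the entries picked afterwards. The median log2 fold change of each list was ranked among 10000 random lists of the same size drawn from 20 bins of like expression. Both steps treat genes as independent. Neighbouring called genes tended to share a direction (77.6% of pairs, against a mean of 50.2% under permutation), so list p-values and percentiles can be too extreme. List members that share a locus entry, where Cuffdiff called none, count among those that did not pass. The text names genes by a rule fixed before the data were examined: the 10 largest increases and decreases among called genes with at least 10 FPKM in the higher group, the 3 called genes with the largest change in each list of at least 3 members (2 if none is called), and nrfA, nrfH, hcp, DVU2544, sat, apsA, apsB, dsrA and dsrB. It took 78 genes; any other gene named was chosen after its values were seen.

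Depth per sample is unknown. FPKM times locus length was searched for whole multiples of a common step among the 200 lowest values of each group, within 0.05 of a step; at best 16.5% of control and 18.0% of FNA values were whole, where chance at 1 step gives 10%, so reads could not be recovered. Alternatives were stricter thresholds, an expression minimum, pseudocounts of 0.1, 1 and 10, recentring on the median ratio, quantile normalization and, added after the data were seen, genes alone at their locus, adjustment over genes with a readable direction and a normal p from the deposited statistic.

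A normal test per gene and the list test were tried on simulated data with 2641 genes, the implied standard errors and 200 changed genes. Cuffdiff's own test, which gave the calls of the main result, was not simulated. It called 0 of 757 genes in shared loci, so the rates given here do not describe its calls. The simulated noise was independent between genes, so changes shared by neighbours were not covered either. A change of 1 on the log2 scale was recovered in 29.2% of genes alone at their locus and 2.2% of genes in shared loci, a change of 2 in 88.2% and 18.3%, and a change of 3 in 98.2% and 54.7%; on average 4.65% of calls were of unchanged genes. A lowered ribosomal list was called in 25 of 25 simulations, and 1 other list was called over 50 simulations. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.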

Results

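The data describe messenger RNA of the sulfate-reducing bacterium Desulfovibrio vulgaris Hildenborough with and without free nitrous acid (FNA), the protonated form of nitrite. Cultures grew without oxygen in lactate and sulfate medium at 30 °C for 26 h, to early log phase at an OD600 of about 0.3. FNA was then given at 4 µg N/L, and 3 samples were taken after 1 h; 3 control samples at 0 µg N/L were taken at the same 27 h of incubation. RNA was sequenced from strand-specific libraries. The authors' deposited table holds 1 FPKM value (fragments scaled by gene length and library size) per gene and group, with the fold change and test of Cuffdiff, so the spread between the 3 samples of a group is seen only through that test. It names its groups by the letters C and F, which were read as control and FNA from their initials; every direction given here rests on that reading. The labels do not say that the samples of a group came from separate cultures grown apart, so a p-value measures the spread between these samples, which may be partly technical. Read depth per sample is unknown. The table lists 3481 genes, of which 2702 were tested.

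The comparison asked which genes respond to FNA within 1 h. Since FNA is the protonated form of nitrite, an effect of FNA could not be told apart from one of nitrite. The hybrid cluster protein gene hcp (DVU2543), which encodes an enzyme annotated as hydroxylamine reductase and spans positions 2653864 to 2655564 of the chromosome in the authors' deposited table, had the largest increase among called genes with at least 10 FPKM in the higher group, from 8.44 FPKM in control to 8589 FPKM with FNA, a 1017-fold difference (log2 9.99, implied standard error 0.59, q = 0.000281). Its neighbour DVU2544, an iron-sulfur cluster-binding protein, rose 265-fold, and the uncharacterised gene DVU0123 rose 796-fold from 1.26 FPKM, per the authors' deposited table. These folds rest on low control values: with a pseudocount of 10 the log2 changes went from 9.99 to 8.86 for hcp, from 8.05 to 6.32 for DVU2544 and from 9.64 to 6.49 for DVU0123, and under quantile normalization DVU0123 (9.92) came before hcp (9.89). The most abundant of the strongly raised messages was zraP (DVU3384), annotated as a zinc resistance-associated protein, which went from 196 to 10054 FPKM in the authors' deposited table. At q under 0.05, 471 genes were called higher and 532 lower with FNA in the authors' deposited table, out of 1036 calls by Cuffdiff's test with Benjamini-Hochberg adjustment. The other 33 calls have an unreadable FPKM in 1 group and were given no direction. Among the calls, 373 genes were at least 2-fold higher and 406 at least 2-fold lower.

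The other genes among the 10 largest increases of called genes with at least 10 FPKM in the higher group were, in the authors' deposited table, msrB (DVU0576, 41.1-fold), which repairs oxidised methionine, the small heat shock protein gene DVU2441 (40.2-fold), the uncharacterised genes DVU2556 (26.0-fold) and DVU4007 (25.2-fold), the HesB-like gene DVU0359 (23.6-fold) and the hydrolase gene DVU2975 (18.2-fold). DVU2556 and DVU0359 were close to the threshold, each with q = 0.0448 in the authors' deposited table. Called decreases were smaller. Among called genes with at least 10 FPKM in the higher group the uncharacterised gene DVU0671 fell most, from 254 to 17.6 FPKM in the authors' deposited table, 14.5-fold (log2 -3.85, implied standard error 0.39, q = 0.000281). The amino acid transporter genes DVU2341 and DVU2343 fell 11.7-fold and 10.1-fold, the thiamine synthesis gene thiE-1 (DVU2091) 10.8-fold, and the tRNA modification gene trmU (DVU0807) 10.6-fold, per the authors' deposited table. The aminotransferase gene DVU2364 (10.1-fold), the iron-sulfur protein gene DVU3033 (8.82-fold) and the transporter gene DVU1245 (8.15-fold) followed in the authors' deposited table. DVU3166 (7.97-fold), which is annotated as an alanyl-tRNA synthetase, and the outer membrane protein gene DVU1260 (7.59-fold) complete the 10 largest decreases of such called genes there. Over all tested genes with both values above 0, called or not and with no minimum FPKM, log2 changes reached down to -6.17. The median log2 fold change over the 2641 tested genes with both values above 0 was -0.12. A normal test of the deposited statistic, added after the data were seen, called 440 genes higher and 476 lower, and 508 higher and 407 lower once recentred on that median.

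**Figure D1:**
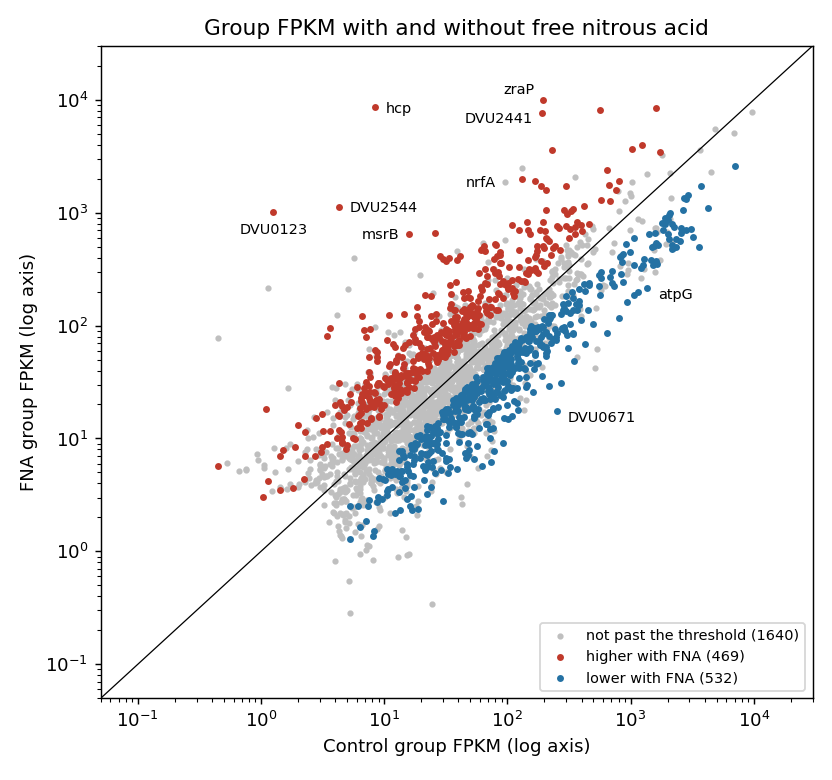
FPKM of each tested gene in the control group (x axis, log scale) and the FNA group (y axis, log scale), 1 point per gene with both values above 0, coloured by the authors' call; the line marks equal values. The hcp gene stands farthest above the line, at 8.44 and 8589 FPKM, and nrfA lies far above it without a call.

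Of the 6 listed genes of nitrite and nitrogen oxide reduction, 3 rose and 3 did not pass the test, and 0 fell; the counts were the same adjusted over the list alone. Besides hcp and DVU2544, the regulator gene DVU2547 of the same region rose 5.13-fold in the authors' deposited table. The cytochrome c nitrite reductase genes, which reduce nitrite to ammonium, were not called: in the authors' deposited table nrfA (DVU0625) had 94.9 FPKM in control and 1875 with FNA, and nrfH (DVU0624) had 131 and 2508, with q = 0.636 and q = 0.672. The implied standard errors of their log2 fold changes, 1.12 for nrfA and 1.06 for nrfH, were above the 0.40 that was the median of genes alone at their locus. The list did not pass Fisher's exact test, one-sided (adjusted p = 0.223), in which its 3 members in shared loci had no call to count. Over genes alone at their locus 3 of 3 rose (Fisher's exact test, adjusted p = 0.0671), and with a normal p from the deposited statistic 5 of 6 passed (Fisher's exact test, adjusted p = 0.00326). Its median log2 fold change of 4.28 was at percentile 99.99 of random lists of like expression. The table places nrfH and nrfA in 1 shared locus on the chromosome, from position 691072 to 693118, and 0 of the 757 tested genes in such shared loci with both values above 0 were called, against 1001 of 1884 such genes alone at theirs; none of the 757 had an unadjusted p under 0.05 by Cuffdiff.

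**Figure D2:**
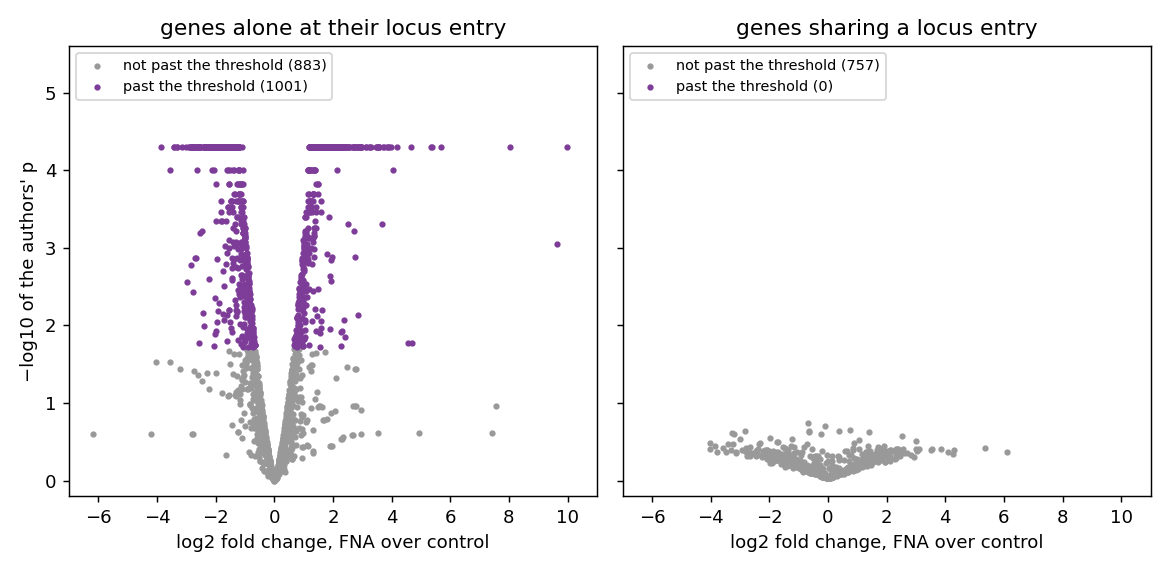
Log2 fold change of FNA over control (x axis) against −log10 of the authors' p (y axis) for genes alone at their locus entry (left) and genes that share one (right), 1 point per tested gene with both FPKM values above 0. Of the 1884 such genes alone at their locus 1001 are past the threshold; of the 757 that share one, 0 are.

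Genes of the Fur regulon, listed for iron uptake, rose as a group, though the called genes named here are not annotated as iron transporters. Of 12 members of the Fur regulon, the genes held down by the iron-sensing repressor Fur, 8 rose, 0 fell, 2 with readable values did not pass, 1 was called without a readable direction and 1 had an unreadable value (8 also adjusted over the list alone). The excess passed Fisher's exact test (one-sided, adjusted p = 0.000237), and the list median was 2.78 on the log2 scale. The flavodoxin gene DVU2680 rose 11.4-fold, from 167 to 1892 FPKM in the authors' deposited table, the diguanylate cyclase gene DVU0763 rose 8.68-fold and the regulator gene DVU2378 rose 7.34-fold. The ferrous iron transporter gene feoB (DVU2571), named after its values were seen, had 38.9 FPKM in control and 455 with FNA in the authors' deposited table and shares its locus (q = 0.628).

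Protein quality control genes rose too. Of 14 genes for chaperones and proteases, 9 rose, 0 fell, 3 did not pass and 2 were called without a readable direction (9 also adjusted over the list alone; Fisher's exact test, one-sided, adjusted p = 0.000213). Besides DVU2441, which reached 7698 FPKM, the disaggregase gene clpB (DVU1874) rose 12.9-fold and htpG (DVU2643), the bacterial Hsp90, rose 6.95-fold in the authors' deposited table. The median of the list was 1.95 on the log2 scale, at percentile 99.99 of random lists of like expression. The co-chaperonin gene groES and the small heat shock gene DVU2442, named after their values were seen, are the calls with no readable FNA value.

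Defences against oxidants and metals gave single raised genes but no list past the threshold. Of 17 genes of peroxide and superoxide defence, 6 rose and 1 fell, and 8 with readable values did not pass; adjusted over the list alone 7 rose (Fisher's exact test, one-sided, adjusted p = 0.142). The PerR regulon gene DVU0772 rose 5.16-fold to 8375 FPKM, the thioredoxin reductase-like gene DVU0283 4.20-fold and the peroxiredoxin gene DVU2247 3.69-fold in the authors' deposited table. Among 8 genes of thiol redox and methionine sulfoxide repair, 3 rose and 5 did not pass (3 also adjusted over the list alone; Fisher's exact test, adjusted p = 0.413). These were msrB, msrA (DVU1984, 7.56-fold) and the thioredoxin reductase gene DVU1457 (5.08-fold), per the authors' deposited table. Of 9 metal handling genes 4 rose and 5 did not pass (4 also adjusted over the list alone; Fisher's exact test, adjusted p = 0.194), led by zraP, the copper-translocating ATPase gene DVU2324 (7.04-fold) and the cation efflux gene DVU0164 (2.51-fold) in the authors' deposited table.

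Genes of the translation apparatus fell together. Of 55 ribosomal protein genes 33 fell, 0 rose, 8 did not pass, 9 were called without a readable direction and 5 had no usable value (33 also adjusted over the list alone; Fisher's exact test, one-sided, adjusted p = 2.88e-15). The 3 with the largest change were rplE (DVU1315), rplV (DVU1308) and rpsH (DVU1317), which fell 5.28-fold, 4.71-fold and 4.65-fold in the authors' deposited table; rplE went from 3190 to 604 FPKM. All 41 ribosomal protein genes with readable values were below control, with a median log2 fold change of -1.72 (-1.60 after recentring, -1.49 after quantile normalization). The 8 that did not pass are all in shared loci, and all 33 readable ones alone at their locus were called lower. Neighbouring genes tended to change together, which Fisher's exact test does not allow for in this or the other lists. Of 24 genes listed as aminoacyl-tRNA synthetases, the enzymes that charge tRNAs with amino acids, 16 fell, 0 rose and 8 did not pass (16 also adjusted over the list alone; Fisher's exact test, adjusted p = 1.06e-05). In the authors' deposited table pheT (DVU2533) was 5.08-fold and pheS (DVU2534) 4.89-fold lower. Genes of the ATP synthase fell as well: 6 of 10 fell, 0 rose, 3 did not pass and 1 was called without a readable direction (6 also adjusted over the list alone; Fisher's exact test, adjusted p = 0.0151). In the authors' deposited table atpG (DVU0776) fell from 1369 to 214 FPKM, atpB (DVU0918) 5.83-fold and atpA (DVU0777) 5.82-fold. The 3 ATP synthase genes that did not pass are in shared loci.

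Of 17 genes of sulfate respiration 9 fell, 0 rose and 6 with readable values did not pass (9 also adjusted over the list alone; Fisher's exact test, one-sided, adjusted p = 0.00433). The membrane complex genes DVU1289, DVU1290 and DVU1286 of the dsrMKJOP operon fell 7.08-fold, 7.03-fold and 6.11-fold in the authors' deposited table. DVU1287 and DVU1288 of this operon, named after their values were seen, share a locus and were not called (q = 0.617 and q = 0.653). They had 367 and 534 FPKM in control and 53.2 and 61.4 with FNA in the authors' deposited table. The sulfite reductase subunit gene dsrA (DVU0402) fell 2.12-fold, from 2090 to 986 FPKM in the authors' deposited table (q = 0.0128). Other genes of the pathway were not called: in the authors' deposited table sat (DVU1295), which activates sulfate, had 4823 FPKM in control and 5459 with FNA (q = 0.911, a shared locus), apsA (DVU0847) had 6910 and 5078 (q = 0.346), apsB (DVU0846) had 9741 and 7860 (q = 0.538), and dsrB (DVU0403), the other sulfite reductase subunit, had 2141 and 1348 (q = 0.127). Differences in fold change between these genes were not tested. At q under 0.01 the list no longer passed Fisher's exact test (adjusted p = 0.177; 0.0039 to 0.252 over the alternatives), and its median of -1.10 was at percentile 9.66 of random lists of like expression.

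Of 18 genes of lactate and pyruvate oxidation, 9 fell, 1 rose and 8 did not pass (10 fell adjusted over the list alone; Fisher's exact test, one-sided, adjusted p = 0.0184). DVU3033 and the lactate permease gene DVU2683 fell 8.82-fold and 5.78-fold, and the lactate dehydrogenase gene ldh (DVU0600) rose 4.73-fold from 5.29 FPKM, per the authors' deposited table. Adding a minimum absolute log2 fold change of 1 ended this call (Fisher's exact test, adjusted p = 0.0565; 0.00207 to 0.0565 over the alternatives). Of 22 hydrogenase genes 2 rose, 8 fell and 11 with readable values did not pass (the same adjusted over the list alone; Fisher's exact test for lower genes, adjusted p = 0.155). The NiFe hydrogenase genes hynB-1 (DVU1921) and hynA-1 (DVU1922) rose 7.12-fold and 6.07-fold in the authors' deposited table, from 10.5 and 8.76 FPKM. The Ech subunit gene DVU0431 fell 3.68-fold. The periplasmic NiFeSe hydrogenase genes hysB (DVU1917) and hysA (DVU1918), named after their values were seen, were called lower. They fell from 706 to 236 FPKM and from 576 to 265 FPKM in the authors' deposited table. Of 11 formate dehydrogenase genes 2 rose, 0 fell and 6 with readable values did not pass (2 also adjusted over the list alone; Fisher's exact test, adjusted p = 0.951): fdnG-1 (DVU0587) and DVU0588 rose 4.21-fold and 4.13-fold in the authors' deposited table. Of 22 genes of transmembrane redox complexes 5 rose, 2 fell and 15 did not pass (the same adjusted over the list alone; Fisher's exact test for higher genes, adjusted p = 0.819), and the 3 with the largest change belong to the Hmc complex, DVU0531, DVU0532 and DVU0534, which rose 3.12-fold, 3.12-fold and 3.07-fold in the authors' deposited table.

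Raised calls were in excess among motility and signalling genes. Of 98 genes for flagella and chemotaxis 39 rose, 5 fell and 49 with readable values did not pass; adjusted over the list alone 41 rose and 5 fell (Fisher's exact test for higher genes, one-sided, adjusted p = 4.54e-07). The chemoreceptor gene DVU2309 rose 9.63-fold, the cheX gene DVU0302 9.32-fold, to 1732 FPKM, and the cheD gene DVU2972 5.12-fold in the authors' deposited table. Of 180 genes for sensor kinases, response regulators and transcriptional regulators, 49 rose, 13 fell and 103 with readable values did not pass (the same adjusted over the list alone; Fisher's exact test for higher genes, adjusted p = 0.000439). The TetR family gene DVU1760 rose 11.9-fold, DVU2378 7.34-fold and the sensor kinase gene DVU3152 5.88-fold in the authors' deposited table. The list medians were 0.88 and 0.61 on the log2 scale, each at percentile 100 of random lists of like expression.

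**Figure D3:**
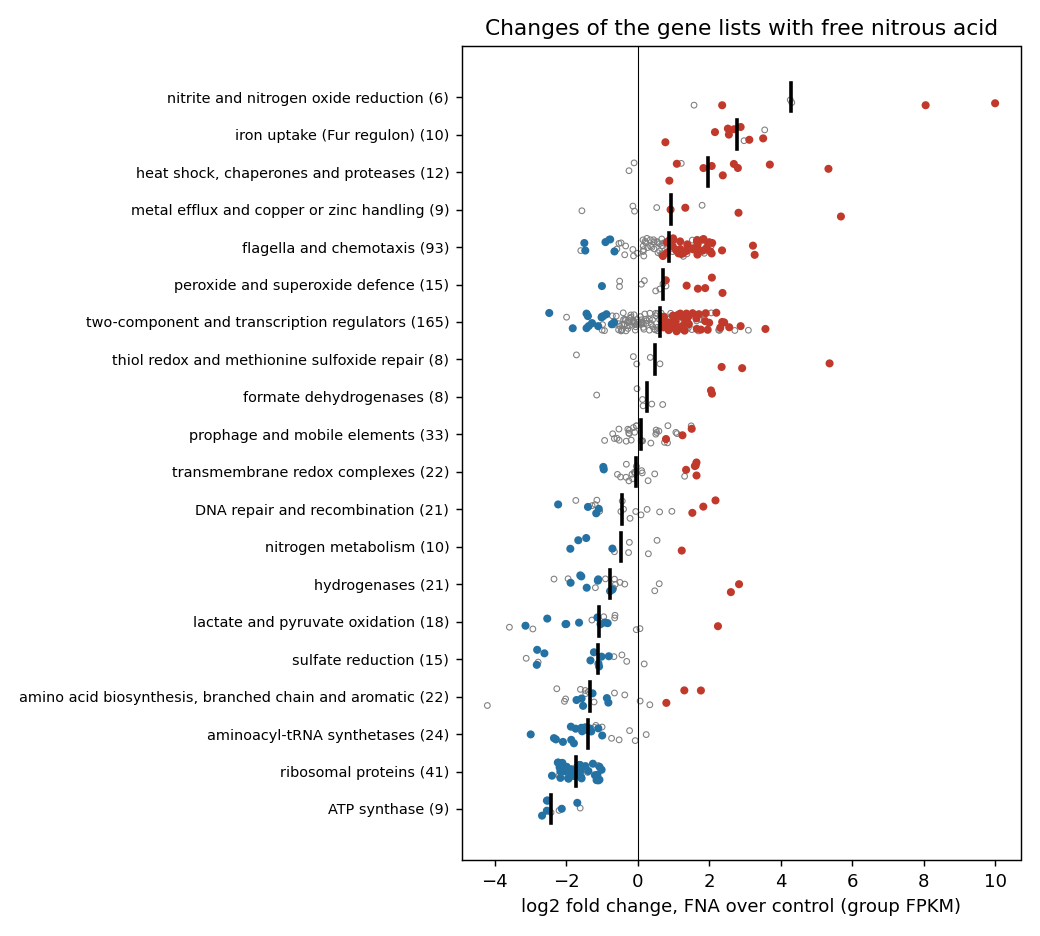
Log2 fold change of FNA over control (x axis) for the members of each gene list with both values above 0 (number in brackets); filled points passed the authors' test (red higher, blue lower), open points did not, and the bar is the list median. Medians run from -2.43 for ATP synthase to 4.28 for nitrite and nitrogen oxide reduction.

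The remaining lists did not pass. Of 21 DNA repair genes 3 rose, 4 fell and 14 did not pass (the same adjusted over the list alone; Fisher's exact test, adjusted p = 1 in either direction). The excinuclease gene uvrC (DVU0801) rose 4.51-fold, the nudix gene DVU2245 rose 3.56-fold and recO (DVU1899) fell 4.68-fold in the authors' deposited table. Of 12 genes of nitrogen metabolism 1 rose and 4 fell (the same adjusted over the list alone; Fisher's exact test for lower genes, adjusted p = 0.345), with nifA-1 (DVU1949), the glutamine synthetase gene glnN (DVU1258) and glnP (DVU0106) 3.70-fold, 3.17-fold and 2.72-fold lower in the authors' deposited table. Of 23 genes for branched chain and aromatic amino acid synthesis 3 rose, 6 fell and 13 with readable values did not pass (the same adjusted over the list alone; Fisher's exact test for lower genes, adjusted p = 0.668). The acetolactate synthase gene ilvB-2 (DVU1376) rose 3.40-fold, whereas trpF-2 (DVU2492) and leuD (DVU2983) fell 3.28-fold and 2.97-fold in the authors' deposited table; the list median of -1.32 was at percentile 0.02 of random lists, and 9 members share a locus. Of 90 genes of prophages and mobile elements 3 rose, 0 fell and 30 with readable values did not pass; adjusted over the list alone 2 rose (Fisher's exact test for higher genes, adjusted p = 1). They were the phage shock gene pspA (DVU2988, 2.84-fold) and the integrase genes DVU2197 (2.38-fold) and DVU0771 (1.73-fold), per the authors' deposited table. The product name of pspA, phage shock protein A, does not by itself mark a prophage gene. Reads of transposases with near-identical copies cannot be assigned with certainty.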

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

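Among genes that Cuffdiff did not test, and which enter no comparison of the report, 9 are listed at 0 in control and at 10 FPKM or more with FNA in the authors' deposited table. They were picked out as a signal with FNA beside a listed 0 in control, but a 0 in this table can be a failed estimate, so they are not shown to be low in control. The highest is the uncharacterised gene DVU0802, at 61.2 FPKM with FNA and 117 bases long. In the opposite direction, 10 untested genes are listed at 0 with FNA and at 10 FPKM or more in control.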

How the results depend on the processing

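Settings on single-gene-locus entries, readable directions and normal p-values, and the pseudocount of 1, were chosen after seeing the data. The 1036 calls became 775 at q under 0.01, 779 with an absolute log2 fold change of at least 1, 969 with at least 10 FPKM in the higher group and 734 with both q and FPKM limits. Adjusting over genes with a readable direction gave 999 calls, and adjusting over genes alone at their locus gave 485 higher and 551 lower genes, among them all 471 and 532 of the main result. A normal p from the deposited statistic gave 916 calls, 62 of them in shared loci. Of the 471 higher and 532 lower calls of the main result it kept 388 and 431. The normal and deposited p lay on the same side of 0.05 in 91.1% of genes alone at their locus and 83.5% of genes in shared loci. Recentring that statistic gave 915 calls, with 55.5% higher against 47.0% in the main result. Quantile normalization turned 0 called genes; recentring alone moves all genes by the same 0.12 and tests nothing of the kind. Of 9 list results, 8 passed at q under 0.01, where sulfate reduction was lost, 8 with the fold minimum and 8 with the recentred normal p, where lactate and pyruvate oxidation was lost each time, and 7 with both q and FPKM limits, where both were lost; the cause was not tested. All 9 passed in the other settings, and under both normal p settings nitrite and nitrogen oxide reduction passed as higher. All 78 named genes kept their direction under each pseudocount and under recentring, and 77 under quantile normalization, where sat, which is not called, went from 0.18 to -0.48; with a pseudocount of 10, 38 moved by more than their implied standard error. The pseudocount does not enter the authors' test, and the planned run with no filter on low values is the authors' own set of tested genes, so neither gave another count; the authors' own calls are the main result. Leaving out replicates, limma without the trend, camera, fry, the megaplasmid share and other splits of the samples were not run, since the table holds no value per sample and no megaplasmid gene. No paired analysis was possible because the columns carry no replicate. Depth is unknown, and unequal depth between samples could not be checked.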

Other observations

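All tests in this part were chosen after the results were seen. Outside the fixed lists, words of product names carried by at least 5 genes alone at their locus were compared with the calls by Fisher's exact test, one-sided, over 161 overlapping words and word pairs in both directions. Of 43 genes with "ABC transporter" in the product name, 27 were called lower (Fisher's exact test, adjusted p = 0.000267, median log2 fold change -1.34), and of all 61 with "transporter", 28 were (Fisher's exact test, adjusted p = 0.0412, median -0.69). In one gene cluster of this kind, DVU2340, DVU2341, DVU2342 and DVU2343 for amino acid uptake, all 4 fell, and DVU2340 went from 56.9 to 8.52 FPKM in the authors' deposited table. Of 7 preprotein translocase genes, which move proteins across the membrane, 6 fell (Fisher's exact test, adjusted p = 0.0412), among them secY, from 3118 to 718 FPKM in the authors' deposited table. Of 5 universal stress protein genes 5 rose (Fisher's exact test, adjusted p = 0.0272, median 1.51). The RNA polymerase genes rpoB and rpoC, singled out after their values were seen, fell 2.94-fold and 3.29-fold in the authors' deposited table, while rpoA (1645 FPKM in control, 679 with FNA, q = 0.722, a shared locus) and rpoZ (256 and 359, q = 0.201) were not called. The elongation factor gene tuf fell from 7046 to 2600 FPKM in the authors' deposited table. The iron-sulfur protein genes DVU1080 and DVU1081, singled out in the same way, share a locus and were not called, with 5.72 and 5.11 FPKM in control and 398 and 211 with FNA in the authors' deposited table.

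Called genes next to each other on the chromosome tended to share their direction. Genes in shared loci or with no readable direction were passed over, so such neighbours need not be adjacent. Of 606 neighbouring pairs of called genes alone at their locus, 77.6% went the same way, against a mean of 50.2% and a highest value of 57.6% over 1000 permutations of the directions. The longest run was 27 genes from DVU1286 to DVU1334, all lower, reaching from the dsrMKJOP genes into the large ribosomal protein cluster. It passes over 19 tested genes, 15 in shared loci and 4 with no readable direction; of the 15, 10 were lower and 5 higher with FNA, among them sat and the regulator gene DVU1331 (63.0 FPKM in control and 537 with FNA in the authors' deposited table, not called). The run around hcp held 6 raised genes from DVU2540 to DVU2549, with a median log2 fold change of 2.83.

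Large changes without a call, such as those of nrfA and nrfH, were mostly in shared loci. Of 165 genes in shared loci with an absolute log2 fold change of at least 1.5 and at least 10 FPKM, 64 were higher and 101 lower with FNA and 0 were called, against 406 of 433 such genes alone at their locus, and 89.7% of genes alone at their locus matched to the 165 on expression and change were called, so the shared entry may be what withholds the call. The median FPKM of the higher group was lower in the 165 genes (56.5) than in such called genes alone at their locus (94.1). Low FPKM is argued against, since of the genes matched to the 111 under 100 FPKM 85.6% were called (resampling interval 81.6% to 94.3% over 87 distinct genes). Gene length was not matched, so low read counts stay open. A larger standard error alone is argued against for 55 of the 165 genes, nrfA and nrfH among them. They pass a normal test of the deposited statistic. For the other 110, which fail that test, it stays open gene by gene. As a set, the 757 tested genes in shared loci with both values above 0 argue against it. Their lowest unadjusted p by Cuffdiff was 0.18, whereas a test that differed only in standard error would still place some genes under 0.05. An effect of FNA or nitrite on the 165 genes stays open, since the normal test finds a change in 55 of them and the authors' test in 0.

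Calls with no readable fold change were mostly of short genes. Of 72 called genes with loci under 300 bases, 41.7% had an unreadable FPKM in 1 group, against 0.31% of 964 longer ones, so a failed estimate for short genes is a candidate explanation. Low expression in the unreadable group stays open, since that is the value missing. No biological explanation was tested.

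Of 74 ribosomal protein, tRNA synthetase and ATP synthase genes with readable values, 73 were lower with FNA than in control. A shift of the whole FNA scale as the whole cause is argued against by its size only, since the median of all genes was -0.12. Taking it off moves all genes alike and left the median of the 3 lists at -1.57 (interval -1.75 to -1.16, resampling 31 blocks of neighbouring members). The 3 lists were picked after their fall was seen, so neither this check nor the next is an independent test. Gene length or expression level as the whole cause is argued against too, within that limit. The median went from -1.69 to -2.05 once the median of other genes of like length and expression was taken off (interval -2.34 to -1.31 by the same blocks). Expression for this match was taken over both groups, so it includes the fall itself. An effect of FNA or nitrite, directly or through slower growth, stays open as a hypothesis, since growth after the addition was not analysed here.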
